A study of Mus musculus with 8 samples.

How the data were processed

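Whole-genome bisulfite sequencing was measured in 8 libraries of mouse CD8 T cells that had been sorted from spleen as CD8+CD90.1+ cells on day 30. The labels put 2 replicates in each of 4 groups, named by the modified gene: Rosa KO, Dnmt3a KO, Tet2 KO and Asxl1 KO. Rosa is a locus that is edited without loss of a known function, and Rosa KO served as the control. Per the labels, DNA was bisulfite treated with an EZ DNA Methylation-Direct kit, libraries were made with the EpiGenome kit and sequenced on a NovaSeq instrument. The submitters list CASAVA 1.7, BSMAP 2.90 and the mouse genome build mm10. Their read filters, trimming and duplicate handling are not given in the sources used here. Bisulfite sequencing reads methylated and hydroxymethylated cytosine alike, so every level is the sum of both.

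Each deposited table lists 1 CpG per line with a position and a pair of numbers, without column names. From the values, 1 column of each deposited table holds expected counts, the estimated number of cytosine plus thymine calls at the CpG (its coverage), of which 1.60% to 2.80% per library are not whole at 2 decimals. The last column of each deposited table holds counts, the number of methylated calls, which are whole and never exceed the coverage. Neither was scaled to library size, and both strands of a CpG share 1 line. The base from which positions are counted is not stated, so coordinates follow the numbering of the deposited tables and may be off by 1 base.

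Unmethylated calls were taken as coverage minus methylated calls. CpGs on the autosomes and chromosome X were kept when their coverage was at least 5 in each of the 8 libraries and outside the top 0.1% of coverage in every library. This kept 17660242 of 21211013 listed CpGs, or 83.3%. Calls were summed over non-overlapping tiles of 1000 bp with at least 3 kept CpGs, which gave 1953507 tiles with a median of 7 CpGs and 140.0 calls per library (67.0 in the shallowest library of a tile). A methylation level is methylated calls over all calls, in percent, and a group's level is the mean of its 2 libraries with their standard deviation (SD).

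Tiles were tested with a quasi-binomial logistic model with 1 level per group. The dispersion came from Pearson residuals of all 8 libraries with 4 residual degrees of freedom and was moderated across tiles as in limma's squeezeVar (prior 1.23 with 65.0 degrees of freedom for tiles and 1.54 with 9.67 for windows). F tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tiles of a comparison. A tile was called at an adjusted p below 0.05 and a difference of at least 20 percentage points. The moderation was checked against limma 3.58.1. The whole test was tried on simulated data with the coverage of these libraries and 1 dispersion (the prior, 1.23) for all tiles and libraries. Groups simulated without a change gave 0 called tiles of 1953507 in each of the 6 comparisons. Tiles or libraries of larger dispersion were not simulated, so this 0 does not bound false calls in the data. Of 200 tiles of intermediate to high level that were lowered by 20, 30 or 40 points, the shares recovered were 25.5%, 76.0% and 96.0% for the Dnmt3a KO design, 30.0%, 87.5% and 99.0% for Tet2 KO, and 33.5%, 80.0% and 96.5% for Asxl1 KO. Gains were not simulated, so these shares do not describe the recovery of higher tiles. Part of the loss at 20 points comes from the threshold, which equals the change: at a threshold of 10 points, 35.0%, 45.5% and 46.5% of the 20-point changes were recovered in the same order. The runs also called between 1 and 5 unchanged tiles.

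The gene table used here (RefSeq, the patch release of the same mouse build) gives gene starts and ends but neither strand nor exons. Promoters, exons, introns and untranslated regions were therefore not analysed, and the test planned for promoters was run on windows at both annotated ends of each gene, from 1000 bp outside to 500 bp inside. There were 40414 windows of 20925 genes with at least 3 kept CpGs and a median of 398 calls per library; windows were called at an adjusted p below 0.05 and a difference of at least 10 points. The low-coordinate and high-coordinate window of a gene are named by their place on the chromosome. Tiles were assigned to a gene when their midpoint lay in its body or within 5000 bp of either end, and the rule as first written had named the upstream side alone.

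The comparisons, tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. 14 lists with 178 genes were used: stem-like and memory, exhaustion and inhibitory receptors, effector, cytokine, chemokine and costimulatory receptors, T cell identity, epigenetic regulators, developmental regulators, imprinted, germline, and markers of B cells, myeloid cells, CD4 and regulatory T cells, NK cells and erythroid cells. For each list, the share of tested tiles that were called was set against 10000 random lists of equal size whose genes were matched on the number of tested tiles (drawn from the 200 nearest genes). These permutation p-values are two-sided by doubling and adjusted over lists and directions; genes are not independent replicates. List windows were also adjusted over the list alone. Named genes are, per direction, the 8 protein-coding genes with the most called tiles, up to 3 members of each list with the most called tiles, members with a called window, the member with the largest window difference where a list had no called tile, the 2 called tiles with the largest difference per direction, and the targeted genes. Some items that this rule names are not reported here.

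Canyons, long regions almost free of methylation, were defined as runs of at least 3500 bp in which the level over 5 neighbouring kept CpGs, pooled over the 8 libraries, stayed at or below 10%. Their flanks are the 1000 bp outside each end. The rule sets no limit on gaps between CpGs, so a run over duplicated sequence with sparse coverage can count as a canyon. Library levels and canyon flanks were compared with exact permutation tests, two-sided. With 2 libraries against 2 these cannot give a p below 0.333.

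The labels do not say whether the 2 replicates of a group came from separate animals, nor whether equal replicate numbers in different groups share anything. The p-values thus speak for these libraries and no wider population. With 65.0 prior against 4 residual degrees of freedom, a tile's p rests mostly on the dispersion common to all tiles. Its own spread between libraries counts little, so a tile whose replicates disagree can still be called. Alternatives covered the coverage minimum (3 and 10), tile size (500 bp and 2 kb), CpGs per tile, the difference thresholds, the groups in the fit, Fisher's exact test on pooled calls, limma on arcsine square root levels, edgeR 4.0.16 on methylated and unmethylated counts, the dispersion floor, a replicate block, thinning to the shallowest library, removal of the genome-wide shift, window, canyon and gene-list settings, and leaving out each library. Leaving out both shallow libraries was added after the data were seen. Chromosome Y and the mitochondrial genome were left out of all tests. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3.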

Results

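The series asks how regulators that are mutated in clonal haematopoiesis, the outgrowth of mutant blood stem cells, shape CD8 T cells during immunotherapy. Dnmt3a is an enzyme that places new methyl groups on cytosine, Tet2 is an enzyme that oxidises methylcytosine on the way to its removal, and Asxl1 is a scaffold of a histone deubiquitinase complex. CpG methylation was measured in sorted splenic CD8 T cells on day 30, with 2 libraries each from Rosa KO (control), Dnmt3a KO, Tet2 KO and Asxl1 KO cells. Positions refer to mouse build mm10.

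Total coverage of the Rosa KO libraries was 4.94e+08 and 2.19e+08 calls (replicates 1 and 2). It was 2.24e+08 and 4.90e+08 for Dnmt3a KO, 5.19e+08 and 5.04e+08 for Tet2 KO, and 4.54e+08 and 4.60e+08 for Asxl1 KO. Mean coverage per listed CpG ran from 10.4 in Rosa KO replicate 2 and 10.6 in Dnmt3a KO replicate 1 to 24.4 in Tet2 KO replicate 1. Each library listed between 21147093 and 21263555 CpGs.

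Over all kept CpGs the level of Rosa KO was 70.2% ± 0.161 (SD, n = 2). Dnmt3a KO lay at 67.6% ± 2.26 (SD, n = 2), a difference of -2.56 points, against a gap of 3.20 points between its own libraries: without Dnmt3a KO replicate 1 it was -0.965, and without replicate 2 it was -4.16. With every CpG given equal weight, the Dnmt3a KO difference was -0.956 points. Tet2 KO lay at 69.5% ± 0.00174 (SD, n = 2), -0.694 points from Rosa KO, and Asxl1 KO at 69.7% ± 0.0189 (SD, n = 2), -0.438 points. Each exact permutation test gave p = 0.333, the smallest this design allows. By place, the Dnmt3a KO difference was -1.55 points in gene bodies (SD of its libraries 0.373, n = 2) and -0.363 points outside genes (SD 0.532, n = 2). The value outside genes is smaller than that SD. Tet2 KO showed the opposite order, with +0.105 points in gene bodies and -1.54 points outside genes, where its level was 71.4% ± 0.0280 (SD, n = 2) against 72.9% ± 0.0210 (SD, n = 2) in Rosa KO. For Asxl1 KO the differences were -0.187 and -0.379 points.

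**Figure D1:**
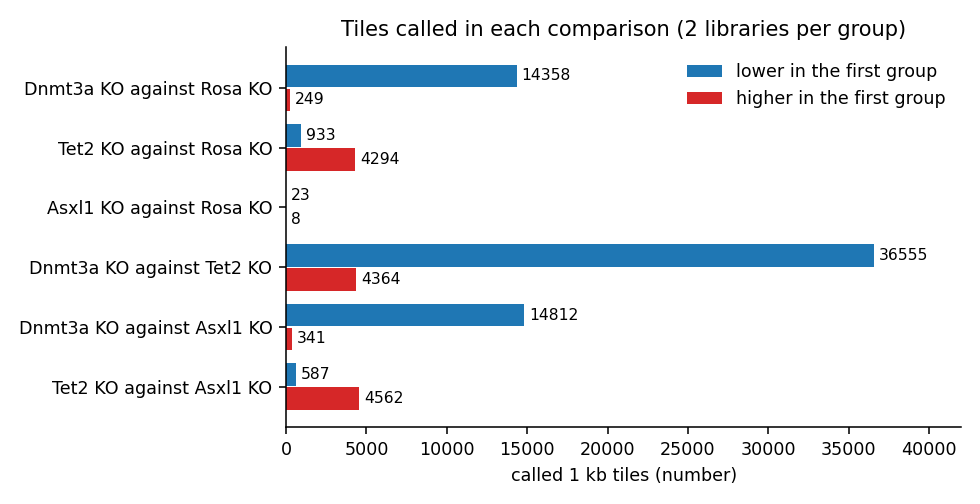
Number of called 1 kb tiles (horizontal axis) in each of the 6 comparisons, lower in the first group in blue and higher in red. Calls fell mostly on the lower side for Dnmt3a KO and mostly on the higher side for Tet2 KO, while Asxl1 KO and Rosa KO differed at 31 tiles.

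The comparison of Dnmt3a KO with Rosa KO asks where CD8 T cells need this enzyme to keep or gain methylation. Methylation was lower at many discrete places in Dnmt3a KO cells. These places lay mainly inside genes and were spread over many of them. Among the preset gene lists, those of stem-like and memory T cells and of T cell identity had the highest share of lower tiles. The edges of the large unmethylated canyons were lower as well, and so was the sequence farther outside them.

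Methylation tables cannot show whether the targeted gene was disrupted, since the read sequences are not part of them. At Dnmt3a itself, 18 of 122 tested tiles were lower in Dnmt3a KO and 0 were higher. Its tile with the largest difference (chromosome 12, 3847000 to 3847999) fell from 84.6% ± 7.63 (SD, n = 2) to 50.5% ± 8.08 (SD, n = 2). That call rested on 3 CpGs and was lost without Rosa KO replicate 1 and without Dnmt3a KO replicate 2. Of the other targeted genes, Tet2 held 1 lower tile of 74, called neither without Rosa KO replicate 2 nor without Dnmt3a KO replicate 1, and Asxl1 held 0 of 61. The window at the high-coordinate end of Tet2 was almost unmethylated in both groups, with 3.37% ± 0.0274 (SD, n = 2) in Rosa KO and 2.44% ± 1.04 (SD, n = 2) in Dnmt3a KO.

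Of 1953507 tiles, 14358 were called lower and 249 higher in Dnmt3a KO, so 98.3% of calls were lower. The higher tiles numbered 378 without Dnmt3a KO replicate 1 and 386 without replicate 2. The median lower tile held 9 CpGs and went from 71.8% in Rosa KO to 44.0% in Dnmt3a KO. At 99.98% of the lower tiles both Dnmt3a KO libraries lay below both Rosa KO libraries, and at 100% of the higher tiles both lay above. The call, made on these same libraries, largely ensures this, so it is no separate measure of agreement between replicates. Gene bodies held 68.7% of the lower tiles against 44.2% of all tested tiles. The median higher tile held 4 CpGs, and gene bodies held 22.5% of the higher tiles. In all, 4070 protein-coding genes had a lower tile and 72 a higher one. The tile with the largest decrease (chromosome 17, 27792000 to 27792999) lay at Ilrun, a regulator of inflammatory signalling, and fell from 91.7% ± 0.833 (SD, n = 2) to 30.5% ± 6.64 (SD, n = 2), with an adjusted p of 3.80e-14 and at least 52 calls per library. A tile outside genes (chromosome 4, 95302000 to 95302999) fell from 86.4% ± 6.15 (SD, n = 2) to 25.5% ± 6.02 (SD, n = 2).

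The genes with the most lower tiles are ranked by number, which favours long genes. Foxp1, a forkhead factor that keeps naive T cells quiescent, had 63 lower tiles of 597 tested, and its strongest (chromosome 6, 99024000 to 99024999) fell from 72.2% ± 6.89 (SD, n = 2) to 18.2% ± 2.12 (SD, n = 2). Etv6, a repressor of the ETS family, had 56 of 242 and reached 16.9% from 65.5%. Cd247, the zeta signalling chain of the T cell receptor, had 33 of 99, and a tile in it (chromosome 1, 165811000 to 165811999) fell from 78.5% ± 1.72 (SD, n = 2) to 23.0% ± 1.90 (SD, n = 2). Ubac2, a membrane protein of protein quality control, had 42 of 148, Prkca, a protein kinase C, had 36 of 403, and Arhgef3, a guanine nucleotide exchange factor, had 35 of 297. Nfkb1, a subunit of the transcription factor NF-kappa B, had 34 of 115, and Bach2, a repressor that holds back effector differentiation, had 35 of 348.

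Stem-like and memory genes held the highest share of lower tiles among the 14 lists. In this list 202 of 1143 tiles were lower, or 17.7%, against a mean of 1.23% in matched random lists, a ratio of 14.3. The adjusted permutation p was 0.00187 (0.0002 before adjustment, the smallest the random lists can give), and 17 of 17 genes had a lower tile. Satb1, a chromatin organiser of T cells, had 30 of 101, and a tile in it (chromosome 17, 51810000 to 51810999) fell from 79.3% ± 2.8 (SD, n = 2) to 18.5% ± 7.30 (SD, n = 2). Lef1, a partner of Tcf7 in Wnt signalling, had 29 of 123, with a tile (chromosome 3, 131171000 to 131171999) that fell from 89.8% ± 0.353 (SD, n = 2) to 43.4% ± 3.49 (SD, n = 2). Lower tiles were also found at the chemokine receptors Cxcr5 (8 of 23) and Ccr7 (5 of 21), and at Klf2, a factor of T cell quiescence and trafficking (3 of 12). S1pr1, the receptor for exit from lymphoid tissue, had 3 of 14 (1 without Rosa KO replicate 1 and 1 without Dnmt3a KO replicate 2), Slamf6, a surface receptor of progenitor cells, had 2 of 38, and Id3, an inhibitor of E proteins in memory cells, had 1 of 11.

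T cell identity genes had 93 lower tiles of 627 (14.8%, ratio 11.3) in 14 of 15 genes, with an adjusted permutation p of 0.00187. Bcl11b, a factor of T lineage commitment, had 25 of 104, and Cd8b1, which encodes a chain of the CD8 coreceptor, had 12 of 24. A tile outside Cd8b1 but within 5000 bp of its end (chromosome 6, 71339000 to 71339999) fell from 74.6% ± 0.0706 (SD, n = 2) to 18.5% ± 2.51 (SD, n = 2). The adhesion receptors Cd6 and Cd2 had 11 and 6 lower tiles. Cytokine, chemokine and costimulatory receptors had 49 of 542 (9.04%, ratio 6.78, adjusted permutation p 0.00187) in 12 of 16 genes. Among these, the adhesion receptor Cd44 had 10 lower tiles (6 without Rosa KO replicate 1), the cytokine receptor chain Il12rb2 had 7 (4 without Dnmt3a KO replicate 2), and Il2ra, a chain of the interleukin receptor for T cell growth, had 6 (1 without Rosa KO replicate 1).

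Exhaustion and inhibitory receptor genes had 63 lower tiles of 1230 (5.12%, ratio 3.81, adjusted permutation p 0.0378) in 15 of 19 genes. Tox, a factor that sets up the exhausted state, had 12 lower tiles and 1 higher of 281. The Ikaros family factor Ikzf2 had 10 of 146. The nuclear receptors Nr4a1, Nr4a2 and Nr4a3, induced by receptor stimulation, had 9, 8 and 6, and a Nr4a2 tile with 42 CpGs (chromosome 2, 57111000 to 57111999) fell from 66.2% ± 5.55 (SD, n = 2) to 13.4% ± 0.717 (SD, n = 2). Effector genes had 27 lower tiles of 485 in 11 of 19 genes, with a ratio of 4.58 and an adjusted permutation p of 0.0885. In that list Runx3, which directs the cytotoxic lineage, had 9 of 67, and Zeb2, a transcriptional repressor, had 5 of 135. The cytokine Tnf had 3 of 13, and fewer without Rosa KO replicate 1 or without Dnmt3a KO replicate 2.

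Epigenetic regulators had 41 lower tiles of 1055 (ratio 2.72, adjusted permutation p 0.171), of which Dnmt3a held 18, the oxidase Tet3 held 13, and Kdm6b, a histone demethylase, held 4 (2 without Rosa KO replicate 2). Developmental regulators had 2 of 888 (ratio 0.151, adjusted permutation p 0.0989), at the homeobox genes Hoxc9 and Lhx2. Imprinted genes had 2 of 760, both at the growth factor receptor Igf2r, and germline genes had 0 of 344. Markers of other blood cells gave 5 of 721 for B cells, among them Cd22 and the B cell receptor chains Cd79a and Cd79b. For myeloid cells they gave 3 of 216, at Cd14, Spi1 and Itgam. They gave 3 of 83 for CD4 and regulatory T cells, all at the CD4 lineage factor Zbtb7b, 1 of 69 for NK cells, at the receptor Klrb1c, and 0 of 46 for erythroid cells. Adjusted permutation p-values of the imprinted, germline and other-cell lists ran from 0.512 to 1.0. Of the 60 named lower tiles, limma called 55, and 48 were called without each of the 4 libraries in turn. The tiles of Cd244a, Cd44, Dnmt3a, Igf2r, Itgam, Lhx2, S1pr1, Slamf6, Tet2, Tnf, Tnfrsf4 and Zeb2 were not.

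**Figure D2:**
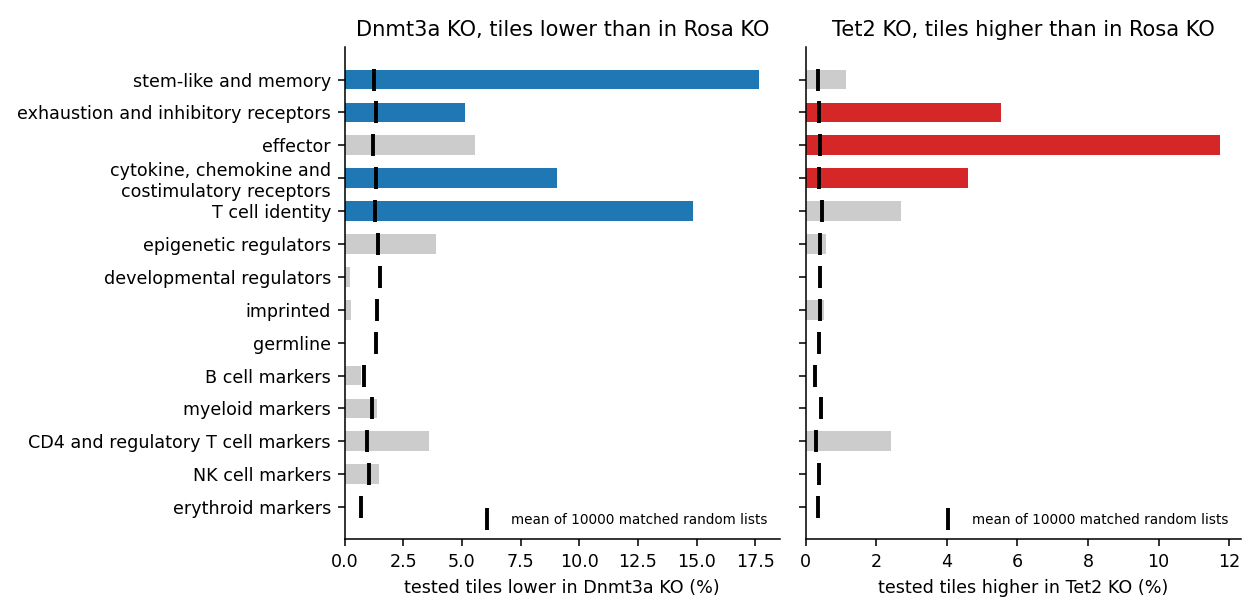
Share of tested tiles (percent) lower in Dnmt3a KO (left) and higher in Tet2 KO (right) for the 14 gene lists, with black ticks at the mean of the matched random lists. Coloured bars mark lists past the adjusted threshold, and the longest bars are stem-like and memory genes at 17.7% for Dnmt3a KO and effector genes at 11.8% for Tet2 KO.

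At gene ends, 807 windows of 786 genes were lower and 5 were higher in Dnmt3a KO. This count rested on the controls: it was 128 in both directions together without Rosa KO replicate 1 and 505 without Rosa KO replicate 2, against 812 with all libraries. Stem-like and memory genes had 9 lower windows of 34 (13 adjusted over the list alone), and the mean of that list was 32.0% ± 0.143 (SD, n = 2) against 41.5% ± 0.645 (SD, n = 2) in Rosa KO. The low-coordinate window of Cxcr5 went from 63.2% ± 2.17 (SD, n = 2) to 25.4% ± 2.72 (SD, n = 2), with an adjusted p of 3.07e-05. Windows of S1pr1, Klf2, Id3, Slamf6 and Ccr7 were lower too, the last from 25% ± 0.456 (SD, n = 2) to 13% ± 0.557 (SD, n = 2). Exhaustion genes had 7 of 38 (9 adjusted over the list alone), and Eomes, a T-box factor shared by memory and exhausted cells, fell from 43.0% ± 2.50 (SD, n = 2) to 9.35% ± 2.07 (SD, n = 2) at its high-coordinate window. The others were Nr4a2, Nr4a3, Irf4, a factor induced by receptor signals, and the inhibitory receptors Cd244a, Cd101 and Havcr2. Of the 32 named windows, those of Cxcr5 (low-coordinate), Eomes and Cd79a stayed called without Rosa KO replicate 1, and 18 stayed called without replicate 2. Without Dnmt3a KO replicate 1 or 2, 25 and 21 stayed called.

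Effector genes had 2 lower windows of 37 (4 adjusted over the list alone): that of Ifng, the gene of interferon gamma, fell from 46.8% ± 2.01 (SD, n = 2) to 28.2% ± 3.93 (SD, n = 2), and that of Tnf from 71.9% ± 2.52 (SD, n = 2) to 48.5% ± 2.08 (SD, n = 2). Both calls were lost without Rosa KO replicate 1. Receptor genes had 4 of 32 (5 adjusted over the list alone), at the costimulatory receptors Icos and Tnfrsf4 and at both ends of the chemokine receptor Ccr2. T cell identity genes had 3 of 30 (5 lower and 1 higher adjusted over the list alone), at Cd6, Cd2 and Cd8b1. Lists of other cells gave Cd79a and Cd79b for B cells (3 adjusted over the list alone), the myeloid factor Spi1 (2 adjusted over the list alone), Cd4 itself (1 adjusted over the list alone) and the erythroid factor Klf1 (1 adjusted over the list alone). NK cell markers had 0 (1 adjusted over the list alone), with 6680 windows at an unadjusted p below 0.05 over all genes in this quasi-binomial test. Hoxa9, a homeobox gene, and Tdrd1, a germline gene, had 1 window each (2 lower and 1 higher, and 1, adjusted over the list alone). Epigenetic regulators and imprinted genes had 0 by either adjustment.

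Tiles higher in Dnmt3a KO were few and thin. The largest difference (chromosome X, 144149000 to 144149999) was from 11% ± 3.81 (SD, n = 2) to 46.8% ± 21 (SD, n = 2) at 3 CpGs, and next came a tile (chromosome X, 96715000 to 96715999) at Gpr165, an orphan receptor, from 48.4% ± 5.61 (SD, n = 2) to 83.4% ± 1.20 (SD, n = 2). Fhit, a large gene at a fragile site, had 2 higher and 3 lower tiles. Serpinb9d, a protease inhibitor, Vmn2r102, a pheromone receptor, Hs6st3, a sulfotransferase, Mlip, a muscle protein, Kcnip4, a potassium channel partner, and Ppfia2, a synaptic scaffold, had 1 each. None of the 9 named higher tiles was called without every library in turn: 0 stayed called without Rosa KO replicate 1 and 1 without Dnmt3a KO replicate 2, against 5 without Rosa KO replicate 2 and 6 without Dnmt3a KO replicate 1.

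Canyons numbered 264, with a median length of 4226 bp. Their interiors were near 0 in all groups, with 1.46% ± 0.0299 (SD, n = 2) in Rosa KO and 1.22% ± 0.136 (SD, n = 2) in Dnmt3a KO. Flanks stood at 39.5% ± 0.408 (SD, n = 2) in Rosa KO and 30.4% ± 0.921 (SD, n = 2) in Dnmt3a KO, a difference of -9.07 points that exceeded the spread between libraries (-6.38 with CpGs of coverage of at least 10). The exact permutation p was 0.333, the smallest possible. At 195 of 264 canyons, or 73.9%, both Dnmt3a KO libraries lay below both Rosa KO libraries, where chance gives 16.7%, and at 11 both lay above. The difference was not confined to the flanks. At 4875 bp from the edge, the farthest point profiled, the Dnmt3a KO libraries were at 53.3% and 56.7% against 62.2% and 61.7% in Rosa KO.

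**Figure D3:**
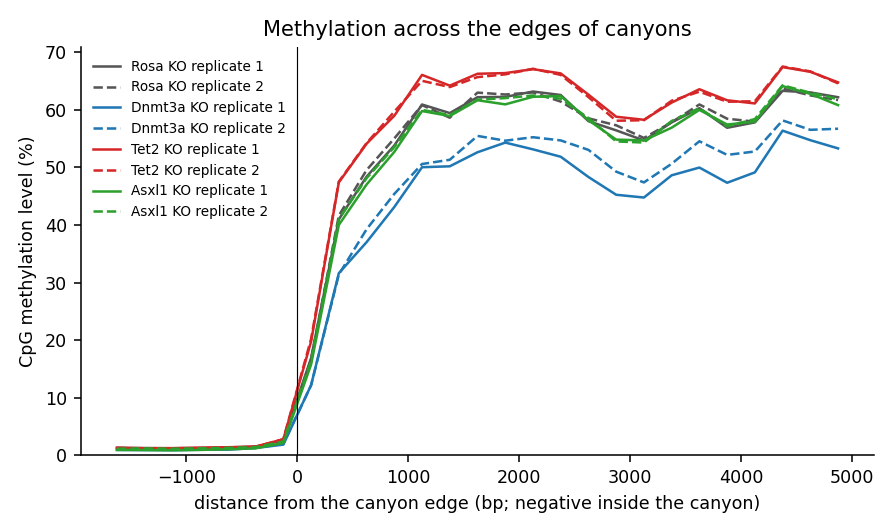
CpG methylation level (percent) by distance from the canyon edge (bp) for the 8 libraries, solid lines for replicate 1 and dashed lines for replicate 2. Outside the edge the Dnmt3a KO libraries run below, and the Tet2 KO libraries above, those of Rosa KO and Asxl1 KO, with flank means of 30.4% and 44.5% against 39.5% and 38.4%.

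The comparison of Tet2 KO with Rosa KO asks where CD8 T cells need this oxidase to become or stay unmethylated. Many tiles were higher in Tet2 KO cells. They were spread over many genes, and the preset lists of effector genes, exhaustion genes and cytokine, chemokine and costimulatory receptors held a larger share than random lists did. A small shift to lower levels was spread outside genes.

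The targeted gene Tet2 held 2 higher tiles of 74, and one (chromosome 3, 133468000 to 133468999) rose from 59.1% ± 4.80 (SD, n = 2) to 88.7% ± 0.214 (SD, n = 2). Its high-coordinate window stayed at 3.28% ± 0.703 (SD, n = 2). Dnmt3a held 2 higher tiles of 122, with a rise from 46.8% ± 4.71 (SD, n = 2) to 75.9% ± 0.0226 (SD, n = 2) in one (chromosome 12, 3868000 to 3868999), and Asxl1 held 0 of 61.

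In total 4294 tiles were higher and 933 lower in Tet2 KO (392 lower without Rosa KO replicate 1), and 1961 protein-coding genes had a higher tile. Limma on the same tiles called 265 higher and 6 lower. The median higher tile held 9 CpGs and went from 45.7% in Rosa KO to 71.7%, while the median lower tile held 4 CpGs and went from 71.1% to 47.0%. Gene bodies held 64.3% of higher tiles and 29.7% of lower ones. At 99.98% of higher tiles both Tet2 KO libraries lay above both Rosa KO libraries, which the call on these same libraries largely ensures. The largest increase (chromosome X, 136990000 to 136990999) was at Slc25a53, a mitochondrial carrier, from 26.1% ± 14.2 (SD, n = 2) to 83.7% ± 3.62 (SD, n = 2) over 4 CpGs. Next came a tile with 20 CpGs (chromosome 9, 120057000 to 120057999) at Cx3cr1, the fractalkine receptor of effector T cells, from 17.7% ± 1.21 (SD, n = 2) to 73.4% ± 1.73 (SD, n = 2), with an adjusted p of 4.40e-29 and at least 296 calls per library.

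Tox had more higher tiles than any other protein-coding gene, 28 of 281, with 0 lower. Its strongest (chromosome 4, 6833000 to 6833999) rose from 26.7% ± 3.24 (SD, n = 2) to 73.5% ± 3.29 (SD, n = 2). Vmp1, a membrane protein of autophagy, had 25 of 101 (15 without Rosa KO replicate 1), and Ubash3b, a phosphatase that dampens T cell receptor signals, had 22 of 157. Atxn1, a transcriptional corepressor, had 21 of 405 (10 without Rosa KO replicate 1). Runx2, a Runt factor active in memory T cells, had 20 of 317, and Rora, a nuclear receptor, had 17 of 730. Coro2a, an actin-binding protein, had 17 of 75. Prex1, an activator of Rac signalling, had 16 of 158, with a tile (chromosome 2, 166673000 to 166673999) that rose from 24.8% ± 5.67 (SD, n = 2) to 69.2% ± 1.52 (SD, n = 2).

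**Figure D4:**
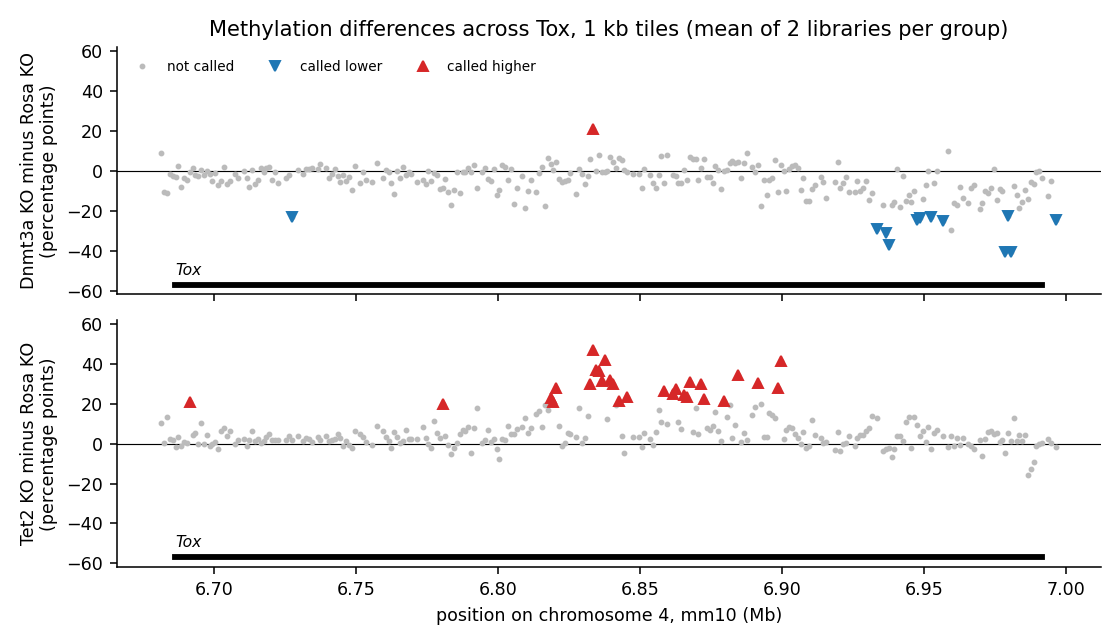
Difference in methylation level (percentage points) from Rosa KO for 1 kb tiles across Tox on chromosome 4 (position in Mb), in Dnmt3a KO above and Tet2 KO below, each point a mean of 2 libraries per group. Tet2 KO had 28 tiles called higher and 0 lower, and Dnmt3a KO had 12 called lower and 1 higher.

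Effector genes had the highest share of higher tiles, 57 of 485 (11.8%) against a mean of 0.396% in matched random lists, a ratio of 29.7, in 16 of 19 genes. The adjusted permutation p was 0.00187 (0.0002 before adjustment, the smallest the random lists can give). Zeb2 had 11 of 135 (7 without Rosa KO replicate 1), with a tile (chromosome 2, 45024000 to 45024999) that rose from 22.6% ± 1.38 (SD, n = 2) to 64.2% ± 2.83 (SD, n = 2). Runx3 had 8 of 67, and the chemokine Ccl4 had 7 of 24 (4 without Rosa KO replicate 1). Exhaustion and inhibitory receptor genes had 68 of 1230 (5.53%, ratio 15.1, adjusted permutation p 0.00187) in 12 of 19 genes. Prdm1, a transcriptional repressor, had 7 of 99, and a tile in it (chromosome 10, 44450000 to 44450999) rose from 11.6% ± 6.56 (SD, n = 2) to 49.1% ± 2.71 (SD, n = 2). Batf, a factor that partners Irf4, also had 7 of 31, and Havcr2 had 4 of 34 (2 without Rosa KO replicate 1 and 2 without Tet2 KO replicate 2).

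Cytokine, chemokine and costimulatory receptors had 25 higher tiles of 542 (4.61%, ratio 12.3, adjusted permutation p 0.00187) in 8 of 16 genes. Il2rb, the shared receptor chain for the growth and survival cytokines of memory cells, had 8 of 43 (fewer without Tet2 KO replicate 1). A tile outside the gene but within 5000 bp of its end (chromosome 15, 78515000 to 78515999) rose from 32.2% ± 7.49 (SD, n = 2) to 78.6% ± 1.82 (SD, n = 2). The costimulatory receptor Tnfrsf9 had 5 of 36 (3 without Rosa KO replicate 1), and Cxcr6, a receptor for tissue residence, had 4 of 12 (2 without Rosa KO replicate 1 and 2 without Tet2 KO replicate 2). Stem-like and memory genes had 13 of 1143 in 9 of 17 genes (ratio 3.24, adjusted permutation p 0.376). Among these, Bcl2, a survival factor, had 4 (2 without Rosa KO replicate 1 and 2 without Tet2 KO replicate 2), with a tile (chromosome 1, 106615000 to 106615999) from 31.9% ± 9.46 (SD, n = 2) to 81.9% ± 1.33 (SD, n = 2). Ccr7 had 2.

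T cell identity genes had 17 higher tiles of 627 (ratio 5.91, adjusted permutation p 0.216), of which Bcl11b held 4 (2 without Tet2 KO replicate 2) and Themis, an adaptor of thymic selection, held 2. Epigenetic regulators had 6 of 1055, among them Dnmt3b, a further de novo methyltransferase, with 1, and imprinted genes had 4 of 760, all at Igf2r. CD4 and regulatory T cell markers had 2 of 83, at Zbtb7b and at Cd40lg, a helper cell ligand. Developmental, germline, B cell, myeloid, NK cell and erythroid lists had 0 in this quasi-binomial test, which gave 271760 tiles at an unadjusted p below 0.05. In the latter lists the largest window differences were +7.12 points at the homeobox gene Hoxd13, -9.68 at the germline gene Taf7l, -11.9 at the B cell factor Pax5, +13.5 at the integrin Itgam, +9.33 at the NK receptor Klra8 and +5.12 at Klf1, none of them called. Limma called 23 of the 39 named higher tiles. Of these 39, 34 were called without each of the 4 libraries in turn; those of Ccl3, Cd40lg, Igf2r and Klrg1 were among the rest.

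At gene ends, 254 windows of 252 genes were higher and 1 was lower in Tet2 KO. The total of 255 rested on single libraries: it was 13 without Rosa KO replicate 1, 108 without Rosa KO replicate 2, 74 without Tet2 KO replicate 1 and 54 without Tet2 KO replicate 2. The high-coordinate window of Ifng rose from 46.8% ± 2.01 (SD, n = 2) to 84.9% ± 1.68 (SD, n = 2), with an adjusted p of 2.53e-05, and the low-coordinate window of Ccr7 from 25% ± 0.456 (SD, n = 2) to 54.1% ± 1.81 (SD, n = 2), with an adjusted p of 8.14e-05. These were the 2 of 18 named windows that stayed called without each library in turn, and limma called 4 of the 18. Effector genes had 7 higher windows of 37 (11 adjusted over the list alone), at Ifng, Tnf, the chemokines Ccl3 and Ccl4 (both ends), the terminal effector receptor Klrg1 and the egress receptor S1pr5. Their mean was 52.5% ± 1.36 (SD, n = 2) against 44.8% ± 0.862 (SD, n = 2) in Rosa KO. Receptor genes had 5 of 32 (7 adjusted over the list alone), among them both ends of Il2rb, the cytokine receptor Il18r1 and Tnfrsf9. Exhaustion genes had 2 of 38 (2 adjusted over the list alone), at Havcr2 and Prdm1, and T cell identity had 1 of 30 (3 adjusted over the list alone). Stem-like genes had 1 (1 adjusted over the list alone), epigenetic regulators had 1 at the maintenance methyltransferase Dnmt1 (1 adjusted over the list alone), and CD4 markers had 1 at Cd40lg (1 adjusted over the list alone). The remaining lists had 0 by either adjustment, with 5507 windows at an unadjusted p below 0.05 over all genes.

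Lower tiles in Tet2 KO were mostly thin. Fyb, an adaptor that links the T cell receptor to integrins, had 5 lower and 2 higher tiles, and its strongest, with 23 CpGs (chromosome 15, 6580000 to 6580999), fell from 43.6% ± 0.982 (SD, n = 2) to 12.2% ± 1.36 (SD, n = 2). Itgb1, an integrin chain, had 3 lower tiles (1 without Rosa KO replicate 1), and one (chromosome 8, 128689000 to 128689999) fell from 55.5% ± 6.02 (SD, n = 2) to 21% ± 1.37 (SD, n = 2). These were the 2 of 13 named lower tiles called without each library in turn; without Rosa KO replicate 1, 3 were called. Galntl6, a glycosyltransferase, Grm5, a glutamate receptor, Negr1, a neuronal adhesion protein, Marchf1, a ubiquitin ligase, and Itgbl1, an integrin-like protein, had 3 each, and Kcnip4 had 2; without Rosa KO replicate 1 or Tet2 KO replicate 1, each of these had at most 1. The largest decreases were at a tile on chromosome 2 (100531000 to 100531999), from 63.1% ± 6.35 (SD, n = 2) to 18.3% ± 18 (SD, n = 2), and on chromosome X (154493000 to 154493999), from 80.8% ± 12.2 (SD, n = 2) to 43.1% ± 13.8 (SD, n = 2), each over 3 CpGs.

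Canyon flanks stood at 44.5% ± 0.463 (SD, n = 2) in Tet2 KO, +5.02 points from Rosa KO (+3.23 with CpGs of coverage of at least 10) and beyond the spread between libraries (exact permutation p 0.333). At 156 of 264 canyons (59.1%) both Tet2 KO libraries lay above both Rosa KO libraries and at 17 below, where chance gives 16.7% each. This difference too reached beyond the flanks. At 4875 bp from the edge the Tet2 KO libraries were at 64.8% and 64.6% against 62.2% and 61.7% in Rosa KO.

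The comparison of Asxl1 KO with Rosa KO asks whether loss of a chromatin scaffold, which does not itself act on DNA methylation, alters the methylome. Very few places differed, too few for the gene lists to be told apart from random ones.

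The targeted gene Asxl1 held 0 called tiles of 61, Dnmt3a 0 of 122 and Tet2 0 of 74. The low-coordinate window of Asxl1 was at 0.874% ± 0.183 (SD, n = 2) in Asxl1 KO and 0.823% ± 0.582 (SD, n = 2) in Rosa KO. Of all tiles, 23 were lower and 8 higher in Asxl1 KO. The total of 31 became 60 without Rosa KO replicate 1, 26 without Rosa KO replicate 2, 30 without Asxl1 KO replicate 1 and 21 without Asxl1 KO replicate 2. Limma called 0 tiles and Fisher's exact test on pooled calls 142, and 106697 tiles had an unadjusted p below 0.05. Lower tiles touched 16 protein-coding genes and higher tiles 3.

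The tile at Fyb that was lower in Tet2 KO was lower here too, at 20.8% ± 1.13 (SD, n = 2) against 43.6% ± 0.982 (SD, n = 2) in Rosa KO, with an adjusted p of 1.21e-07. It was the 1 named tile of 16 that stayed called without each of the 4 libraries in turn. Lower tiles were also called at Cd247, with a fall from 75.7% ± 7.30 (SD, n = 2) to 48.1% ± 9.86 (SD, n = 2) (chromosome 1, 165796000 to 165796999), and at Zbtb20, a zinc finger repressor of memory cells (chromosome 16, 43432000 to 43432999). Others were Pak6, a kinase of actin control, Ppp1r3f, a phosphatase subunit, and a tile shared by the annexin Anxa9, the ceramide synthase Cers2 and LOC115489748, a predicted gene, which went from 49.3% ± 7.13 (SD, n = 2) to 24.8% ± 5.39 (SD, n = 2). Higher tiles lay at Cep97, a centriole protein, Cth, an enzyme of cysteine synthesis, and Map3k8, a kinase of inflammatory signalling. Without Asxl1 KO replicate 2, 1 of the 16 named tiles stayed called, without replicate 1 it was 7, and without Rosa KO replicates 1 and 2 it was 5 and 3. Outside genes, the largest decreases were on chromosome 9 (61758000 to 61758999, from 52.1% ± 10.6 to 23.2% ± 1.23, SD, n = 2; and 60543000 to 60543999, from 73.7% ± 8.20 to 45.7% ± 2.11, SD, n = 2). The largest increases were on chromosome X (19967000 to 19967999), from 38.3% ± 12.8 (SD, n = 2) to 86.4% ± 14.5 (SD, n = 2), and on chromosome 7 (77229000 to 77229999), from 44.8% ± 1.06 (SD, n = 2) to 69.7% ± 1.71 (SD, n = 2).

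All 14 gene lists had 0 called tiles in Asxl1 KO, where random lists also had almost none. With tiles called from 10 points on, 2 lists passed the adjusted threshold, T cell identity (lower) and effector genes (higher), each with an adjusted permutation p of 0.0028, and with 20 kb around genes 1 list did. At gene ends, 0 of 40414 windows were called by the quasi-binomial test, limma or edgeR. Fisher's exact test on pooled calls gave 72 windows, and 1956 had an unadjusted p below 0.05. Adjusted over the list alone, 1 effector window was lower, that of Tnf at 58.0% ± 4.95 (SD, n = 2) against 71.9% ± 2.52 (SD, n = 2), and 1 receptor window, that of Tnfrsf4 at 24.2% ± 2.08 (SD, n = 2) against 35.6% ± 3.74 (SD, n = 2), and 0 in the other lists. Window differences with the largest size per list included -5.97 points at Cxcr5, -9.53 at the inhibitory receptor Tigit, +12.8 at Il18r1 and -10.6 at Cd6. They were +6.4 at the Asxl1 relative Asxl3, +10 at the neural factor Sim1, +8.45 at the imprinted Snrpn and -11.5 at the meiosis gene Sycp3. Markers of other cells gave -7.51 at Cd22, -6.84 at Spi1, +14.1 at Cd40lg, -8.66 at the NK receptor Ncr1 and -5.54 at Klf1. Canyon flanks were at 38.4% ± 0.654 (SD, n = 2), -1.04 points from Rosa KO (-0.580 without Asxl1 KO replicate 1 and -1.65 with CpGs of coverage of at least 10, exact permutation p 0.333). At 75 of 264 canyons (28.4%) both Asxl1 KO libraries lay below both Rosa KO libraries and at 37 (14.0%) above, where chance gives 16.7% each.

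Comparing the knockouts with each other asks how far they differ without use of the Rosa KO levels. A loss in Dnmt3a KO alone also makes a tile lower than in Tet2 KO, so these counts alone cannot show opposed changes. Tiles higher in Tet2 KO than in Rosa KO were held by 9 of 17 stem-like genes and 16 of 19 effector genes. Dnmt3a KO and Tet2 KO differed most, with 36555 tiles lower (1.87% of all tested tiles) and 4364 higher (0.223%) in Dnmt3a KO. List counts below were not set against random lists. All 19 exhaustion genes, all 19 effector genes, all 17 stem-like genes and all 15 T cell identity genes held tiles lower in Dnmt3a KO than in Tet2 KO, 207, 123, 297 and 163 of them, and 0 higher. Receptor genes had 110 lower in 15 of 16 genes and 0 higher, epigenetic regulators 64, CD4 markers 8, developmental regulators 10 and myeloid markers 10, each with 0 higher. Imprinted genes had 10 lower and 3 higher, B cell markers 11 and 1, germline genes 1 and 1, NK cell markers 1 and 0, and erythroid markers 0 and 0. Gene-end windows numbered 2698 lower and 147 higher. Against Asxl1 KO, Dnmt3a KO had 14812 lower and 341 higher tiles (588 higher without Dnmt3a KO replicate 2), and Tet2 KO had 587 lower and 4562 higher.

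The 3 comparisons with Rosa KO share its 2 libraries, which cannot be split into parts of 2, so overlap between them includes shared noise. Simulated groups without a change, with 1 dispersion for all tiles, gave no called tile to share. Tiles lower in Dnmt3a KO and higher in Tet2 KO numbered 356, against 31.6 for lists drawn independently, 25 were lower in both (6.86 for independent lists), 15 were higher in both (0.547 for independent lists, a ratio of 27.4 against 11.3 for the opposed tiles), and 0 were higher in Dnmt3a KO and lower in Tet2 KO. Across tiles, the differences of Dnmt3a KO and Tet2 KO from Rosa KO correlated at r = 0.126, against r = 0.547 from the shared control in simulation. Tiles are not independent replicates. For Dnmt3a KO with Asxl1 KO the values were 0.405 and 0.535, and for Tet2 KO with Asxl1 KO 0.501 and 0.61. Changes in 1 knockout alone also lower r, so a lower r does not show opposed changes. The covariances, in the same order of pairs, were 4.185, 10.81 and 12.4, against 11.95, 11.93 and 11.96 in simulation. The differences from simulation were -7.761, -1.117 and 0.4356. Unlike r, a covariance is left nearly unchanged by changes in 1 knockout alone. The value for Dnmt3a KO with Tet2 KO thus argues against such changes as the whole account over all tiles. It points to no single tile and rests on a simulation with 1 dispersion. Of the 23 tiles lower in Asxl1 KO, 13 were lower in Dnmt3a KO, against 0.169 for independent lists.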

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

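Of the tests below, the overlap within classes for comparisons with no library in common was chosen after the result was seen; the others were set before.

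The differences between knockouts were large when each pair was tested directly: 40919 tiles between Dnmt3a KO and Tet2 KO, 15153 between Dnmt3a KO and Asxl1 KO, and 5149 between Tet2 KO and Asxl1 KO. At canyon flanks the difference of Dnmt3a KO from Tet2 KO was -14.1 points. Both Dnmt3a KO libraries lay below, and both Tet2 KO libraries above, both Rosa KO libraries, and this difference was not tested. In data outside the tests, CpGs of the mitochondrial genome (263 to 277 per library) had a mean level of 49.4% ± 0.799 (SD, n = 2) in Dnmt3a KO, 47.7% ± 0.441 (SD, n = 2) in Rosa KO, 45.3% ± 0.411 (SD, n = 2) in Tet2 KO and 47.3% ± 1.43 (SD, n = 2) in Asxl1 KO. These levels are high for a genome often described as nearly unmethylated. Mean coverage there ran from 154 to 185 calls per CpG and hardly followed total depth. It was 173 in Rosa KO replicate 2 and 154 in Dnmt3a KO replicate 1, the shallow libraries, and 181 to 185 in the others. The highest coverage of any listed CpG was 249. Whether counts there were limited, and the cause of these levels, were not tested.

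Tiles lower in Dnmt3a KO and higher in Tet2 KO numbered 356, more than independent lists share. Shared Rosa KO libraries move both differences the same way (r = 0.547 in simulation) and so cannot produce opposed calls; the count without a library in common (Dnmt3a KO with Rosa KO, Tet2 KO with Asxl1 KO), 626 or 18.7 times the 33.5 of independent lists, was bound to be higher and does not test them. Both kinds of call also need tiles of similar level, CpG number and place, and lists drawn within such classes shared 115.2, so the excess fell to 3.09 ± 0.164 (counting error) times. This lies above the limit of 3 set beforehand by less than its counting error, which treats tiles as independent. Without a library in common the excess within classes was 4.88 ± 0.195 times. The classes were set by Asxl1 KO levels, which also enter that Tet2 KO call, so this value is not independent of the classes. The classes thus account for part of the overlap and, as drawn, left an excess in both counts. Whether other classes could account for all of it is not decided. Sites at which Dnmt3a and Tet2 act in opposition remain possible, which methylation levels alone cannot show.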

How the results depend on the processing

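Every alternative ran as planned, and leaving out both shallow libraries was chosen after seeing the data. A library left alone in its group is assumed to vary like the other groups. Unless a construction is named, the cause of a change was not tested.

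Counts of called tiles followed the difference threshold by construction, and they also moved with tile size. At 10 points they were 42148 for Dnmt3a KO against Rosa KO, 24705 for Tet2 KO, 211 for Asxl1 KO, 132174 for Dnmt3a KO against Tet2 KO, 47769 for Dnmt3a KO against Asxl1 KO and 28056 for Tet2 KO against Asxl1 KO. At 30 points they were 3478, 731, 1, 11967, 3719 and 755. With 500 bp tiles they were 27214, 12682, 81, 71947, 28797 and 13020, and with 2 kb tiles 5126, 1484, 3, 16524, 5468 and 1351. Limma gave 271 for Tet2 KO against Rosa KO (6 lower, 265 higher), 0 for Asxl1 KO and 352 for Tet2 KO against Asxl1 KO. Fisher's exact test, which ignores spread between libraries, gave 142 for Asxl1 KO, and tiles of at least 1 CpG gave 20. Tiles shared by Dnmt3a KO (lower) and Tet2 KO (higher) were 4914 at 10 points and 56 with 2 kb tiles. With the libraries left out in turn, the counts in the order above ran from 11788 to 16074, 4227 to 5351, 21 to 60, 40770 to 45555, 14469 to 17912 and 5021 to 5414.

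The replicate block, which pairs libraries of equal number, gave 14495, 5155 and 202 for Dnmt3a KO tiles, Tet2 KO tiles and Tet2 KO windows. Deviations of equal numbers hardly correlated over single tiles (from -0.0190, for Rosa KO with Dnmt3a KO, to 0.00314). Sampling noise in single tiles holds such correlations near 0, so they cannot exclude a shared deviation.

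The Dnmt3a KO level difference was -0.956 with equal CpG weights and ran from -4.16 to -0.965 in the leave-outs. That of Tet2 KO was -0.561 at a coverage of 10 and ran from -0.808 to -0.580. That of Asxl1 KO was -0.662 at a coverage of 10 and -0.276 with equal CpG weights, and ran from -0.552 to -0.324.

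Called windows of Dnmt3a KO were 230 at 20 points, 453 without both shallow libraries and 1494 by Fisher's test, and 128 to 844 in the leave-outs. Those of Tet2 KO were 55 at 20 points, 925 by Fisher's test, 55 by limma, 458 by edgeR and 116 with calls thinned to the shallowest library, and 13 to 108 in the leave-outs. Thinning changes depth alone, and it left 14822 called tiles for Dnmt3a KO. Asxl1 KO had 72 by Fisher's test and 0 in every leave-out.

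The canyon flank difference of Dnmt3a KO was -6.38 at a coverage of 10, -7.68 with 500 bp flanks and -8.00 for canyons of doubled minimum length (leave-outs -9.72 to -8.42). That of Tet2 KO was 3.23, 4.38 with a 5% limit and 4.46 for doubled length (leave-outs 4.69 to 5.35). That of Asxl1 KO was -1.65 at a coverage of 10 (leave-outs -1.50 to -0.580). Lists past the threshold at 10 points were 7 for Dnmt3a KO (4 as reported), 6 for Tet2 KO (3) and 2 for Asxl1 KO (0), the last 1 with 20 kb around genes, and no list lost its call.

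Reversed were only net called tiles (higher less lower) of genes with few calls in Dnmt3a KO: Hs6st3 ran from -2 to 1 in the leave-outs, Fhit was 1 by Fisher's test, and Kcnip4 was -1 after thinning. Of other single-item values, 642 for windows and 2058 for tiles kept direction and call, and 249 and 320 kept direction but lost the call.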

Other observations

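Tests on equal CpG weights, depth, canyon flanks, conversion, Rosa KO replicate 1 alone and gene-poor bins were chosen after the result was seen.

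Some genes held both kinds of change; the genes of this paragraph were chosen after their values were seen. Foxp1 had 63 tiles lower in Dnmt3a KO and 12 higher in Tet2 KO, 5 of them the same tile, and 115 lower in Dnmt3a KO than in Tet2 KO. Rora had 25 and 17, Runx2 had 19 and 20, and Nfatc1, a factor activated by calcium signals, had 14 and 13, with 3 shared tiles each. Ksr1, a scaffold of MAP kinase signalling, had 21 and 6, and Prkch, a protein kinase C of T cells, had 31 and 5. In Nfatc1 a tile with 32 CpGs (chromosome 18, 80617000 to 80617999) rose from 33.9% ± 2.19 (SD, n = 2) in Rosa KO to 86.2% ± 1.65 (SD, n = 2) in Tet2 KO.

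The following canyons were picked from the longest after their values were seen, and no test asked which kinds of gene hold canyons. At Ikzf1, a lymphoid zinc finger factor (11923 bp), the flanks were at 35.5% in Rosa KO, 21.3% in Dnmt3a KO and 44.2% in Tet2 KO, and at Ets1, a lymphoid ETS factor (11418 bp), at 33.3%, 24.9% and 45.3%. At Zfp36l2, an RNA-binding protein that destabilises transcripts (8336 bp), they were at 57.6% ± 0.410 (SD, n = 2), 29.1% ± 0.915 (SD, n = 2) and 67.0% ± 4.13 (SD, n = 2). At Irf2bp2, a corepressor (7188 bp), they fell from 32.3% ± 0.306 (SD, n = 2) to 4.70% ± 0.132 (SD, n = 2) in Dnmt3a KO and stood at 31.6% in Tet2 KO. The longest run, 75112 bp over Srp54b, rested on as few as 27 calls at its flanks. At the next, 12598 bp at Ms4a6c, a membrane protein of the MS4A family, with as few as 72 calls, flanks differed from Rosa KO by -4.50 points in Dnmt3a KO, -4.55 in Tet2 KO and -4.33 in Asxl1 KO. At Tnrc18 (8816 bp), a chromatin protein, the differences were -2.64, +4.34 and +1.62 points.

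Replicate 1 of Dnmt3a KO had a pooled level 3.20 points below replicate 2. Equal CpG weights removed 80.8% of the gap, as a coverage tilted to CpG-dense tiles would do: relative coverage of this library was 0.825 in sparse tiles and 1.55 in the densest. A gap of 0.613 points remained with equal weights, against at most 0.0313 points in the other groups, and the tilt leaves it unexplained. The Rosa KO libraries differ as much in depth, but by 0.228 points in pooled level and 0.00964 points in mean CpG level. This argues against low depth alone as the cause, but 1 pair of libraries cannot exclude it. A larger share of cells without Dnmt3a in replicate 1 is possible, but the gap at canyon flanks, 1.3 points, is too close to the highest of other groups, 0.925, to decide.

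Tiles at 50% to 80% were lower by 2.29 points in Tet2 KO (a difference of -2.29) although most of its called tiles were higher. A difference in bisulfite conversion would move the most methylated tiles the same way, and these differed by +0.728. Sorting of tiles by a pool that holds the compared libraries is excluded too, since classes made from Asxl1 KO gave -2.28, and the shallow Rosa KO replicate 2 likewise, since replicate 1 alone gave -2.27. A hypothesis that the loss follows partially methylated domains was tried on 100 kb bins sorted by Asxl1 KO level: of 5 equal classes the lowest differed by -2.88 and the highest by +1.28, a contrast of -4.16, which is consistent with it. Gene-poor bins gave a contrast of -1.60 but no steady order (-3.06, -2.60, -0.503, +0.430 and -1.45), and a difference in cell divisions, which could act through such domains, was not tested.

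At the 23 tiles lower in Asxl1 KO, of which 13 were lower in Dnmt3a KO, Tet2 KO lay below Rosa KO at 39.1%, with mean differences from Rosa KO of +2.10 points in Tet2 KO and -21.1 points in Dnmt3a KO.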
